A study of Mus musculus with 12 samples.

How the data were processed

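Tumors from mice with orthotopic grafts of AsPC-1 or BxPC-3 cells were profiled by RNA sequencing, with 3 control and 3 ATO libraries for each line. Groups and replicate numbers were taken from the sample titles. The dose and schedule of ATO and what the control mice received are not given in the sources used here. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these libraries. Per the labels' protocols, libraries were made from total RNA with a SMARTer mRNA kit. The labels name the mouse as the organism, and the cell lines are human. Per the submitters' processing notes, the genome builds GRCm38, mm10 and hg38 were used, with no role stated. The aligner, the counting tool, the annotation and the treatment of reads from mouse cells are not given in the sources used here.

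The authors deposited 1 table of FPKM values for each line, with genes in rows and the 6 libraries in columns. The tables state no unit, and FPKM was read from the values: each value was a whole number of reads multiplied by a constant of the library and divided by a whole gene length. Each gene in a table had a value above 0 in at least 4 of its 6 libraries. In 1 cell a space within the number was removed. All identifiers started with ENSG, and 0 of those in both tables matched the 55450 identifiers of the mouse name table at hand, so no gene is named.

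Reads and gene lengths were recovered from these steps with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, trying lengths up to 30000 bases and calling a value whole within 0.05 reads or closer. In this way 99.9% of the values came out whole in each table. On 3662 simulated genes, 99.97% of lengths and 99.99% of read counts came out right. The library constants did not follow the sum of the recovered reads. That sum was 86.3% to 88.7% of the total implied by the constant in AsPC-1 control libraries and 105% to 118% in AsPC-1 ATO libraries. It was 76.7% to 98.1% in BxPC-3 control libraries and 72.6% to 79.3% in BxPC-3 ATO libraries. How the authors set the constant is not stated, so the fold changes of the named genes and the medians by length are also given after rescaling where they could be. Whether a unit is a read or a read pair is not stated either.

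Each line was tested alone with limma 3.58.1 in R 4.3.3 (eBayes with trend) on log2(FPKM + 1), over genes of at least 1 FPKM in 3 or more libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of low genes. The difference between lines was the line by treatment term in 1 model of the 12 libraries over genes in both tables. The tables may have been scaled separately, and the line term takes up a constant difference. These designs and the alternatives for them were fixed before the data were examined. They had foreseen counts or normalized values, and the test for normalized values was used. Alternatives were a replicate block, quantile normalization, no filter, a pseudocount of 0.1, no trend, a filter of at least 5 FPKM, 1 model over 12 libraries, a fold change of at least 2, and leaving out each library in turn. Voom with limma on recovered reads, with median-ratio size factors and genes of at least 1 CPM in 3 libraries, was added after the data were seen, as was every analysis without the library labelled BxPC-3 control 3 other than the fit of its own line. The rank of abundant genes, the length classes and the cell cycle lists were also added after the data were seen.

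The rule for named genes, set before the data were examined, took the genes with the largest changes past the threshold or, if none passed, those with the smallest unadjusted p in each direction with a mean of at least 1 FPKM in the higher group. As the files pair no names with identifiers, only the first gene in each direction of each line is printed, none is printed for the difference between lines, and loci without names could not be left out. The 35 gene lists fixed beforehand, which are lists of names, the title gene and the shares of mouse and human genes were not analysed here. In their place, 3 lists of identifiers for the cell cycle phases G1, S and G2M were taken from the human marker pairs distributed with the R package scran, keeping identifiers that were markers of 1 phase only. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry.

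Single values per library were compared with two-sided exact permutation tests of the difference of means, where 3 against 3 libraries cannot give a p under 0.1. Differences between lines in such values were tested by regrouping the libraries within each line, which stands for no change in either line. The limma test was tested on simulated data, in 10 draws per line with 100 genes changed 2-fold and 100 changed 4-fold. With the 6 AsPC-1 libraries and 15396 to 15460 genes, it recovered on average 22.7% of the 2-fold changes and 73.0% of the 4-fold changes, with 0 to 8 unchanged genes called. With 5 BxPC-3 libraries and 14798 to 14845 genes, it recovered 16.0% and 69.9%, with 0 to 9 unchanged genes called. The simulated noise was drawn for each gene alone, so these counts do not cover variation shared across genes. Read sampling noise was added to a spread that already included it. The 66 pairs of libraries were compared by a chi-square of their reads over genes with more than 20 reads, and the lowest median over genes was 1.95, so no library was counted as a repeat of another.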

Results

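RNA was sequenced from tumors of mice that carried human pancreatic ductal adenocarcinoma cells in the pancreas, with or without arsenic trioxide (ATO), an arsenic compound used in the treatment of acute promyelocytic leukemia. The tumors came from the lines AsPC-1 and BxPC-3, both established lines of this cancer. The 12 libraries fell into 4 groups of 3, control and ATO for each line. The values were FPKM, here reads of a gene scaled by the length of the gene and by a constant of the library. This constant did not follow the sum of the recovered reads. The series title concerns glutathione S-transferase theta 2 and resistance to ATO, and the comparisons ask which genes differed between ATO and control tumors in each line. The files give genes only as identifiers that start with ENSG and do not pair them with names, so the title gene, gene families and cell type markers were not analysed here. Genes are described below by identifier, length, abundance and membership of identifier lists.

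The deposited values covered 26820 genes in AsPC-1 and 27457 genes in BxPC-3, with 23445 in both. The reads behind the FPKM values were recovered from their steps. They summed to 13763260, 15723218 and 11219576 in AsPC-1 control replicates 1 to 3, and to 16177136, 15057388 and 14003953 in the AsPC-1 ATO replicates. In BxPC-3 they summed to 16093521, 19306887 and 16791514 in the control replicates, and to 18303138, 15386411 and 19001674 in the ATO replicates.

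The library labelled BxPC-3 control 3 had the gene profile of the AsPC-1 libraries. Across 16745 genes, which are not independent replicates, its log2(FPKM + 1) values correlated with those of the 6 AsPC-1 libraries at r = 0.946 to 0.973, and with those of the other 5 BxPC-3 libraries at r = 0.691 to 0.722. A set of 128 genes more than 32-fold higher in AsPC-1 than in those 5 BxPC-3 libraries had a median of 18.6 FPKM in this library. The same set had medians of 15.3 to 21.1 FPKM in the AsPC-1 libraries and 0.088 to 0.113 FPKM in the other BxPC-3 libraries. A set of 129 genes more than 32-fold higher in BxPC-3 had a median of 0.0804 FPKM in this library, against 12.8 to 16.1 FPKM in the other BxPC-3 libraries and 0.0506 to 0.0732 FPKM in AsPC-1. Both sets were chosen without this library. It stayed in the BxPC-3 control group, as labelled, and the BxPC-3 tests are also given without it.

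**Figure D1:**
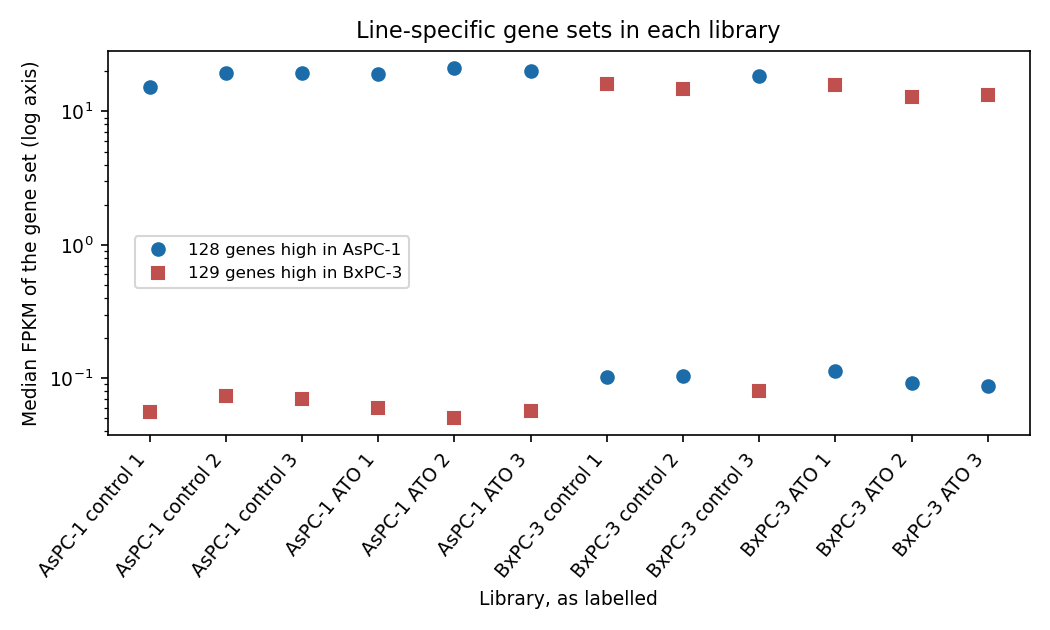
Median FPKM (log axis) of 128 genes high in AsPC-1 (circles) and 129 genes high in BxPC-3 (squares) in each of the 12 libraries, named as labelled. The library labelled BxPC-3 control 3 had 18.6 FPKM for the AsPC-1 set and 0.0804 FPKM for the BxPC-3 set, within or next to the range of the AsPC-1 libraries.

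In AsPC-1 tumors, the most abundant genes held a larger share of the reads in ATO than in control libraries. The 20 most abundant of the genes in both tables, ranked by their mean share over the 12 libraries, held 20.5% ± 2.43 of the reads in control tumors (SD, n = 3) and 36.7% ± 2.22 in ATO tumors (SD, n = 3). All 3 ATO libraries, at 34.2%, 38.5% and 37.4%, lay above all 3 control libraries, at 18.1%, 20.4% and 22.9%. The difference of 16.3 percentage points exceeded the spread between replicates, and its two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. These genes were 297 to 22767 bases long, with 1 of the 20 under 300 bases.

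In BxPC-3 tumors the same 20 genes held 24.0% ± 7.14 of the reads in control libraries (SD, n = 3) and 14.6% ± 3.83 in ATO libraries (SD, n = 3), a difference of -9.45 percentage points with a two-sided exact permutation p of 0.2. The library labelled BxPC-3 control 3 had the highest share of the group, 30.9%. Without it the difference was -6.03 points (exact permutation p = 0.3, n = 2 and 3). The change with ATO differed between the lines by 25.7 percentage points (two-sided exact permutation test over 400 regroupings within the lines, p = 0.01), and by 22.3 points without the library labelled BxPC-3 control 3 (200 regroupings, exact p = 0.015). These regroupings stand for no change with ATO in either line. A p for an equal change in both lines was not computed.

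**Figure D2:**
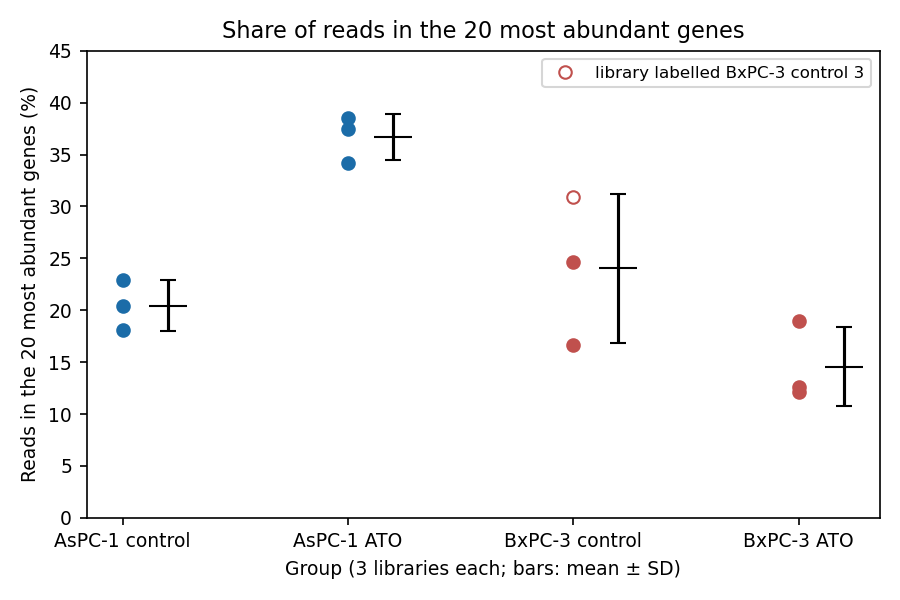
Percent of each library's reads in the 20 most abundant genes, by group, with points for libraries and bars for the mean ± SD of 3 libraries. The AsPC-1 ATO libraries (34.2% to 38.5%) lay above the AsPC-1 controls (18.1% to 22.9%), and the open circle is the library labelled BxPC-3 control 3 (30.9%).

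As first tested, without a replicate block, no gene passed an adjusted p of 0.05 between ATO and control in AsPC-1 tumors. Of 15287 genes tested with limma and Benjamini-Hochberg adjustment, 0 passed, 3210 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0528. With voom and limma on the recovered reads, 19 of 15726 genes passed, all 19 higher in ATO. In the planned setting with a replicate block 1193 genes passed, 903 higher and 290 lower. With voom and the block 3441 passed, 1164 higher and 2277 lower. The replicate numbers were not taken to pair the libraries. With genes of at least 5 FPKM in 3 libraries only, 77 of 7422 passed, 76 higher and 1 lower, and at an adjusted p under 0.10 the count was 163, with 157 higher and 6 lower. The median log2 fold change of the tested genes was 0.12 on the deposited scale, -0.021 after quantile normalization and -0.041 on the recovered reads. The count at an unadjusted p under 0.05 was 1191 without ATO replicate 2, 1533 without ATO replicate 3, 1730 without control replicate 1 and 5007 without ATO replicate 1.

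The AsPC-1 gene with the smallest p among those higher in ATO was ENSG00000212360, a gene model of 104 bases. Its FPKM values were 0, 0.538 and 0.760 in control tumors and 6.88, 9.82 and 8.49 in ATO tumors, or 0, 1 and 1 reads against 11, 13 and 11. Its log2 fold change was 2.74 (SE 0.24, limma adjusted p = 0.0528), and 2.61 with quantile normalization, in which it passed. Among all tested genes on the deposited scale it did not pass without a replicate block, and passed with the block (limma adjusted p = 0.0336). Its adjusted p was under 0.05 in 3 of the 11 settings in which it was tested, with a range of 0.0136 to 0.197. It fell under the filter on low values with voom and in each fit that left out an ATO library. The gene with the smallest p among those lower in ATO was ENSG00000263535, of 672 bases, with 6.29 ± 1.49 FPKM in control tumors and 2.24 ± 0.0269 in ATO tumors (SD, n = 3 each). It had 55 to 75 reads in the control libraries and 19 to 23 in the ATO libraries. Its log2 fold change was -1.15 (SE 0.19, limma adjusted p = 0.0724), -1.31 with quantile normalization and -1.61 with voom on the recovered reads, and 2 of its 15 settings gave an adjusted p under 0.05 (range 0.0028 to 0.26).

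In BxPC-3 tumors 0 of 15135 genes passed an adjusted p of 0.05 in limma, 507 had an unadjusted p under 0.05, and the smallest adjusted p was 0.765. Without the library labelled BxPC-3 control 3, 0 of 14633 genes passed and 758 had an unadjusted p under 0.05. With voom on the recovered reads the count was 0 of 16456, with 431 at an unadjusted p under 0.05, and 0 of 16214 with 917 without that library. Without ATO replicate 2 the count at an unadjusted p under 0.05 was 174, without ATO replicate 3 it was 178, and without ATO replicate 1 it was 1083.

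The BxPC-3 gene with the smallest p among those higher in ATO was ENSG00000229064, of 151 bases, with 0.348, 0.526 and 0 FPKM in the control libraries and 5.16, 4.38 and 2.79 in the ATO libraries. It had 1, 2 and 0 reads against 18, 14 and 11. Its log2 fold change was 1.98 (SE 0.28, limma adjusted p = 0.765), 1.92 with quantile normalization and 1.80 without the library labelled BxPC-3 control 3. The gene with the smallest p among those lower in ATO was ENSG00000252062, of 101 bases, with 4.45 ± 1.83 FPKM in control libraries and 0.85 ± 0.0885 in ATO libraries (SD, n = 3 each). Its log2 fold change was -1.49 (SE 0.30, limma adjusted p = 0.765), and -1.58 with quantile normalization. It had 6 to 10 reads in the control libraries and 2 in each ATO library, and without the library labelled BxPC-3 control 3 it fell under the filter on low values. Neither gene passed in any setting in which it was tested.

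The response to ATO was then compared between the lines gene by gene. The line by treatment term passed an adjusted p of 0.05 in 0 of 16745 genes in limma, with 2575 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0941. Without the library labelled BxPC-3 control 3 it passed in 0 of 16600 genes, with 2577 at an unadjusted p under 0.05. With voom on the recovered reads it passed in 0 of 17450 genes, with 2408 at an unadjusted p under 0.05, and in 0 of 17319 without that library, with 2802 and a smallest adjusted p of 0.0523.

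As first tested, no gene passed the threshold in either line, so the lists of called genes shared 0 genes. At an unadjusted p under 0.01, among 12845 genes tested in both lines, 498 were higher and 119 lower with ATO in AsPC-1, and 17 were higher and 32 lower in BxPC-3. The BxPC-3 counts were 36 and 45 without the library labelled BxPC-3 control 3. With voom on the recovered reads they were 3 and 13, and 23 and 88 without that library, so the BxPC-3 balance also moved with the scaling. The balance in AsPC-1 depended on the scaling, with 400 higher and 602 lower with voom on the recovered reads. With quantile normalization it was 337 higher and 199 lower, among the genes also tested in BxPC-3 without that library. On the deposited scale the lines shared 0 genes in the same direction, where independent lists would share 0.659 higher and 0.296 lower. With voom and without the library labelled BxPC-3 control 3, they shared 0 higher and 5 lower, against 3.81 lower for independent lists (one-sided Fisher's exact p = 0.333). Genes higher in AsPC-1 and lower in BxPC-3 numbered 7, against 1.24 for independent lists (one-sided Fisher's exact p = 0.000183), and without the library labelled BxPC-3 control 3 they numbered 4, against 1.62 (one-sided Fisher's exact p = 0.0773). Without that library they numbered 10 against 1.49 with quantile normalization (one-sided Fisher's exact p = 1.85e-06) and 15 against 2.39 with voom (one-sided Fisher's exact p = 1.27e-08). With voom on all libraries they numbered 6, against 0.368 (one-sided Fisher's exact p = 7.24e-07). Genes lower in AsPC-1 and higher in BxPC-3 showed no such excess. They numbered 0 on the deposited scale, against 0.157 for independent lists. With voom and without that library they numbered 1 (one-sided Fisher's exact p = 0.639), and in the other settings 0. These p-values treat genes as independent, which they are not. Pairs of splits of the libraries were run for the correlation between lines, not for these counts. There, 29 of 100 pairs, the real one included, were at least as far from 0. Across the 12845 genes the log2 fold changes of the lines correlated at Pearson's r = -0.348 and Spearman's rho = -0.327, and at r = -0.272 and rho = -0.225 across 12436 genes without that library.

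Median changes with ATO differed by gene length. The tests of this difference per library could not give a p under 0.1 within a line, and those between the lines did not pass 0.05. The median log2 fold change was 0.34 over 1429 genes under 300 bases, 0.32 over 2353 genes of at least 300 and under 1200 bases, and 0.074 over 11496 genes of 1200 bases or more, beside 0.12 over all tested genes. These AsPC-1 medians were 0.17, 0.15 and -0.060 after quantile normalization and 0.31, 0.33 and -0.070 on the recovered reads, so the sign for long genes depended on the scaling. In BxPC-3 the medians were -0.18 over 1243 genes, -0.063 over 2104 and 0.025 over 11777, and -0.15 over 1084, -0.081 over 1918 and 0.0048 over 11620 without the library labelled BxPC-3 control 3. With all BxPC-3 libraries they were -0.16, -0.084 and 0.039 after quantile normalization and -0.24, -0.095 and 0.039 on the recovered reads. Without that library they were -0.11, -0.037 and 0.026 after quantile normalization and -0.23, -0.13 and 0.0087 on the recovered reads. A score for each library, the median deviation of its short genes from their means over the line minus that of its long genes, was -0.12 ± 0.17 in AsPC-1 control and 0.19 ± 0.19 in AsPC-1 ATO libraries (SD, n = 3 each, two-sided exact permutation p = 0.2). It was 0.14 ± 0.18 in BxPC-3 control and -0.097 ± 0.33 in BxPC-3 ATO libraries (SD, n = 3 each, exact permutation p = 0.3). That BxPC-3 change of -0.24 was -0.093 without ATO replicate 2, -0.42 without ATO replicate 1, and -0.16 without the library labelled BxPC-3 control 3 (exact permutation p = 0.5). The difference between the lines in this change was 0.55 (exact permutation p = 0.06), and 0.46 without the library labelled BxPC-3 control 3 (exact permutation p = 0.15).

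**Figure D3:**
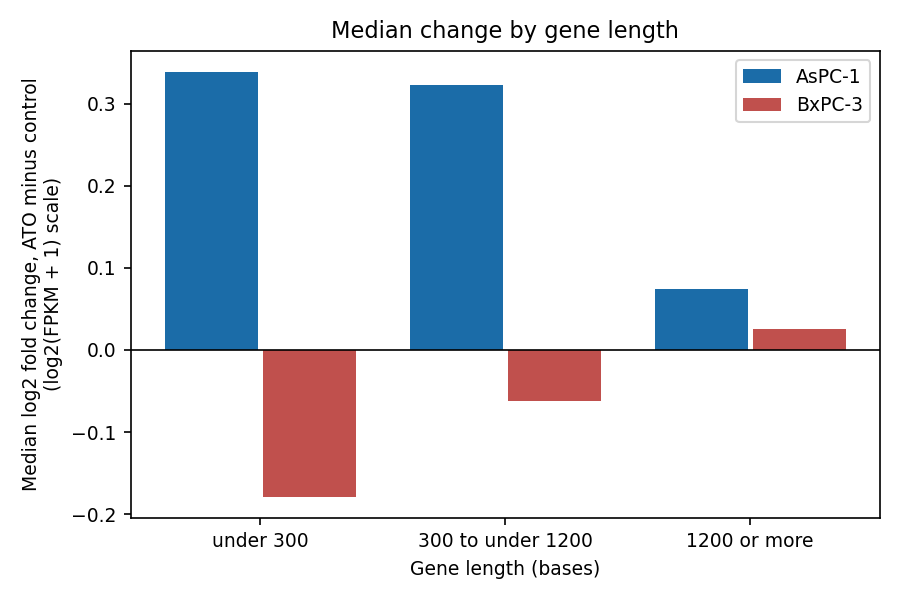
Median log2 fold change, ATO minus control on the log2(FPKM + 1) scale, of the tested genes in 3 classes of gene length, for AsPC-1 and BxPC-3. Bars are medians over genes and carry no error; the medians of genes under 300 bases were 0.34 in AsPC-1 and -0.18 in BxPC-3, and the AsPC-1 bar of 0.074 for long genes was -0.060 after quantile normalization.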

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

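The test below was chosen after the data were seen. The change with ATO in the share of reads held by the 20 most abundant genes differed between the lines: it was 16.3 percentage points in AsPC-1 and -9.45 in BxPC-3, a difference of 25.7 points (two-sided exact permutation test, p = 0.01). Without the library labelled BxPC-3 control 3 the difference was 22.3 points (exact permutation p = 0.015). Both p-values are against no change with ATO in either line, not against an equal change in both.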

How the results depend on the processing

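Of 128 alternative values computed, 111 were labelled the same and 0 reversed. A count of 0 was the same only if it stayed 0, and a named gene if it kept its side of the threshold. A measure per library was the same if it moved by less than its spread. Counts of genes could not be labelled reversed. The setting with a fold change of at least 2 only removes calls, so it had to leave a count of 0 the same. The count of AsPC-1 genes past an adjusted p of 0.05, 0 as first tested, was 1 with quantile normalization, 77 with at least 5 FPKM in 3 libraries, 163 at an adjusted p under 0.10 and 19 with voom on recovered reads. It ranged from 0 to 1 over the fits that left out a library, with 1 gene without ATO replicate 1. The filter tested fewer genes; for the others the cause was not tested. With a replicate block the AsPC-1 count was 1193 (903 higher, 290 lower), and 3441 with voom on recovered reads and the block (1164 higher, 2277 lower). The block left the counts in BxPC-3 and between the lines at 0. Deviations of libraries with the same number correlated across genes at 0.331, 0.2 and 0.0814 in AsPC-1 and at 0.0326, 0.0655 and 0.0123 in BxPC-3. Not every AsPC-1 library correlated best with its own number: control replicate 3 did so with ATO replicate 2 (0.214). The numbers were therefore not taken to pair the libraries. BxPC-3 control replicate 3 correlated best with ATO replicate 1 (0.0287). The BxPC-3 values could not decide the pairing, as the control mean behind these deviations included the library labelled BxPC-3 control 3. Neither this check nor the block was run without that library. BxPC-3 and the difference between lines kept counts of 0 in all settings run. At an unadjusted p under 0.01 the lines shared 0 genes in the same direction, except 5 with voom and without the library labelled BxPC-3 control 3, where the cause was not tested. The correlation of changes between lines, -0.348, was -0.272 without the library labelled BxPC-3 control 3, -0.266 with quantile normalization and without it, -0.291 with voom and -0.215 with voom and without it; the cause was not tested. The alternatives foreseen for the named lists, the title gene and the shares of mouse and human genes, and the count-only tools, were not run. With 11 to 18 reads in the higher group for the first AsPC-1 and BxPC-3 genes higher in ATO, depth limits such short genes.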

Other observations

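The cell cycle lists and most tests below were chosen after the results were seen. Those of gene length, of the most abundant genes and of regroupings for the correlation between lines were also added after the data were seen. For these, the expected outcomes were written before their results. In AsPC-1 tumors, 79 tested members of the G1 list had a median log2 fold change of -0.14 with ATO, against 0.12 over all tested genes (camera adjusted p = 1.65e-05 at the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.253), and fry gave an adjusted p of 0.362. At an unadjusted p under 0.05, 14 members were lower and 3 higher, and 0 passed when adjusted over the list alone. The S list (80 members, median 0.16, camera adjusted p = 0.80) and the G2M list (68 members, median 0.11, camera adjusted p = 0.80) did not pass in AsPC-1. In BxPC-3 the camera adjusted p was 0.749 for G1, 0.749 for S and 0.065 for G2M, and 0.887, 0.642 and 0.642 without the library labelled BxPC-3 control 3.

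The library labelled BxPC-3 control 3 resembled the AsPC-1 libraries. A mixture with AsPC-1 RNA is argued against by the genes high in BxPC-3, which stood at a median of 0.622% of their level in the other BxPC-3 libraries, next to the 0.393% to 0.593% in AsPC-1 libraries. A swap with an AsPC-1 library of the series is argued against, since 0 of the 6 AsPC-1 libraries were closer to BxPC-3, and an AsPC-1 library deposited under another name as well, since the lowest median chi-square per gene was 2.62. A wrong label, or a swap with an AsPC-1 library outside the series, may account for it: its lowest correlation with an AsPC-1 library was 0.946, above its highest with a BxPC-3 library. Between AsPC-1 control (0) and ATO (1) it lay at 0.577, in a range where control libraries reached 0.438 and ATO replicate 1 lay at 0.36, so its treatment was not read from it, and no biological explanation was tested.

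Changes with ATO correlated negatively between the lines across genes. Without the library labelled BxPC-3 control 3, 42.6% of genes still changed in the same direction relative to the medians of the lines. The library labelled BxPC-3 control 3 is argued against as the whole source, as the correlation without it was -0.272. The sampling of libraries could account for it. Pairs of splits, 1 in each line, were formed without that library. Of 100 pairs, 29 gave a correlation at least as far from 0, the real pair among the 29. The highest other was 0.584 in size, so chance cannot be excluded. Some of the 100 pairs kept the real split of 1 line. Whether an axis of variation between tumors of 1 group is the source cannot be told apart, because differences between AsPC-1 libraries of the same group correlated with the BxPC-3 change at up to 0.145 in size, less than the change with ATO but not near 0. A difference between the lines in their response remains open and was not tested apart from these.

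In AsPC-1 an unadjusted p under 0.05 was reached by 21.0% of 15278 genes with a recovered length, where 5% would be expected of unchanged and independent genes. A trend with gene length is argued against as the whole source, since 19.9% of genes remained under that p after its removal from each library, and so is the scale set by the 20 most abundant genes, with 20.2% after leaving them out and rescaling by the median ratio. The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 3210 genes, 0 of the 9 other splits gave as many, and the highest other split gave 2231. An effect of ATO may account for the excess and remains a hypothesis, since differences between the tumors other than ATO were not tested.

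In BxPC-3, 4 of 10 splits, the real one among the 4, gave at least the 507 genes of the real one at an unadjusted p under 0.05, with 1310 in the highest other. Without the library labelled BxPC-3 control 3 it was also 4 of 10, with 758 genes in the real split and 4050 in the highest other. These splits are too few for a share under 0.05. For the difference between lines, 5 of 100 splits, the real one and 4 of the 99 drawn at random, gave at least the real 2575 genes, with 4351 in the highest other. Without that library it was 7 of 100, the real one included, with 2577 genes in the real split and 4974 in the highest other. The highest other split in each case kept the 3 AsPC-1 control libraries on 1 side, and so held the real AsPC-1 grouping. Other splits above the real one, at 4032 genes with all libraries and 4910 without that library, did not hold it. These splits therefore cannot decide on chance, which cannot be excluded in either case. Without that library, the highest BxPC-3 split, ATO replicates 2 and 3 against ATO replicate 1 and both controls, called 594 genes at an adjusted p under 0.05 in limma, against 0 in the real one. It was picked as the highest of 10, and it points to a structure among these 5 libraries that does not separate all ATO from all control libraries. Because ATO replicates 2 and 3 formed 1 side of it, the split cannot tell whether this structure is related to ATO.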
